A study of Homo sapiens with 6 samples.

How the data were processed

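The screen was run in 94T778 cells, a well-differentiated liposarcoma cell line, carrying the genome-wide GeCKOv2 CRISPR knockout library, whose A and B parts hold different single guide RNAs (sgRNAs) for the same genes. Per the labels, cells that carried the A or the B part were grown for 10 days, in which sgRNAs against essential genes are lost, and were then kept for 72 h in 0.05% DMSO or in 10 µM of the MDM2 inhibitor named Nutlin3R in the sample labels and Nutlin3a in the series description. Genomic DNA was extracted and the integrated sgRNA cassette was amplified and sequenced in 3 samples per group. The labels give the replicates as separate samples and do not say that they are separate cultures. The p-values of tests that compare libraries therefore measure the spread between these samples, which may be technical.

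Per the submitters' processing notes, the authors' steps included bcl2fastq, FastQC 0.11.2, Bowtie2 2.2.3 and SAMtools. The genome build and the rules for assigning a read to an sgRNA are not given in the sources used here, and no coordinates are given. The deposited table holds whole-number read counts per sgRNA and library, not normalised, as its values show. It lists 119461 sgRNAs, 63950 of the A part and 55511 of the B part, of which 1000 are non-targeting and the rest are assigned to 21353 targets, 1892 of them microRNAs. The 3 treated columns carry the name IC50 with a replicate number and were matched to the Nutlin samples as the only condition other than DMSO. For 14397 sgRNAs (12.1%) a second annotation in the table differs from the library target, and the library target was used. In 3 of the 6 libraries the counts sum to exactly 20000000, for a reason not given in the sources used here. The total counts were 14427522, 20000000 and 15562410 in the DMSO libraries and 20000000, 20000000 and 10624012 in the Nutlin libraries, or 88.9 to 167 reads per sgRNA. Reads are amplified copies without molecular identifiers, so the depth in reads overstates the number of independent templates, and no counting intervals are given.

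The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test and TMM scaling, for the 113495 sgRNAs with at least 60 counts summed over the 6 libraries (995 of them non-targeting). Fold changes are Nutlin over DMSO, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Genes were tested by robust rank aggregation of their sgRNA ranks, separately for depletion and enrichment (both one-sided, with an alpha of 0.25), for the 20145 targets with at least 3 tested sgRNAs. The p-values came from 2000000 random draws of ranks, and the smallest p these can give is 5e-07. They treat the sgRNAs of a gene as independent and do not measure the spread between samples. Abundances are CPM (counts scaled to a common library total) on the TMM scale, given as mean ± SD of 3 libraries, either summed over the sgRNAs of a gene or averaged per sgRNA over a gene list. The log2 fold changes with a standard error (SE) come from an edgeR fit on counts summed per gene, run beside the rank aggregation.

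Gene lists (37, with the non-targeting sgRNAs as one of them) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, fry, and a camera test on a mean z per gene were run beside it. The test on a mean z takes genes as its units and not samples. It used the same preset correlation, which over the genes of a list corrects less than over its more numerous sgRNAs. The pattern that collects the microRNA targets was narrowed after the target names were seen and before any test, because it also took LETM1, LETM2, LETMD1 and MIR205HG. The abundance of a list in DMSO was set against 10000 random lists of as many genes. Single values per library were compared by exact two-sided permutation tests, for which 3 against 3 allows no p below 0.1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.

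Groups, tests, gene lists, thresholds and most alternatives were set before the data were examined. The genes named are 12 core genes of the p53 pathway and of this tumour type, the 10 genes with the lowest depletion p and the 10 with the lowest enrichment p (ties ordered by the median log2 fold change), list members past the threshold, and leading members of any list that camera called; these make 31 genes, of which some are not reported here. Other members of a list are named only where it is said that they were chosen after their values were seen.

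The tests were run on simulated counts with 50 genes changed per fold size and direction. Each changed gene had 6 tested sgRNAs, and every one was shifted by the full fold. Genes with fewer tested sgRNAs or with inactive sgRNAs were not among the changed genes. With negative binomial counts at the dispersion of these libraries (19788 genes tested), rank aggregation recovered 0% of genes lowered 4-fold, 28% of genes raised 4-fold, 0% of genes lowered 10-fold and 70% of genes raised 10-fold, with 0 false calls. The test on summed counts recovered 2%, 28%, 32% and 88% of the same classes, with 4 false calls. With counts simulated as multiples of the read number at which each library's histogram peaks (20023 genes tested), rank aggregation recovered 2%, 84%, 42% and 100%, with 2 false calls, and summed counts recovered 10%, 94%, 24% and 100%, with 1 false call.

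The alternatives were DESeq2 1.42.0 size factors, total counts or non-targeting sgRNAs for scaling, no filter or a minimum of 300 counts, the replicate number as a block, each library left out, the DESeq2 Wald test, other settings of the rank aggregation, either library part alone, and microRNA targets left out. Counts divided by the spacing of the histogram peaks, and sgRNAs whose annotations match, were added after the data were seen. The plasmid library and cells sampled before treatment were not used here, so losses during the first 10 days are seen only as low abundance in DMSO.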

Results

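The screen asked which gene losses sensitise 94T778 liposarcoma cells to Nutlin, a small molecule that blocks the binding of MDM2 to p53 and so releases p53. Each library measured the abundance of 119461 sgRNAs in genomic DNA after 72 h in 0.05% DMSO (n = 3) or 10 µM Nutlin (n = 3). An sgRNA against a gene whose loss sensitises the cells should be less abundant after Nutlin, and one against a gene whose loss protects them more abundant. The DMSO libraries held 14427522, 20000000 and 15562410 reads and the Nutlin libraries 20000000, 20000000 and 10624012.

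The reads per sgRNA were not spread smoothly. In DMSO replicate 1 the histogram of reads per sgRNA peaked at 80 and again at 160, and in Nutlin replicate 3 at 77 and 150. In units of this spacing the libraries held between 1.17 and 1.54 units per sgRNA. Across sgRNAs, which are not independent replicates, the Spearman correlation between libraries of one group was 0.401 to 0.449, and between libraries of different groups it was 0.386 to 0.436. Summed per gene, it was 0.489 to 0.554 within and 0.498 to 0.523 between groups. By these sums the DMSO libraries (0.535 to 0.554) were closer to each other than any pair from different groups. The Nutlin libraries (0.489 to 0.514) were about as far apart as libraries of different groups.

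**Figure D1:**
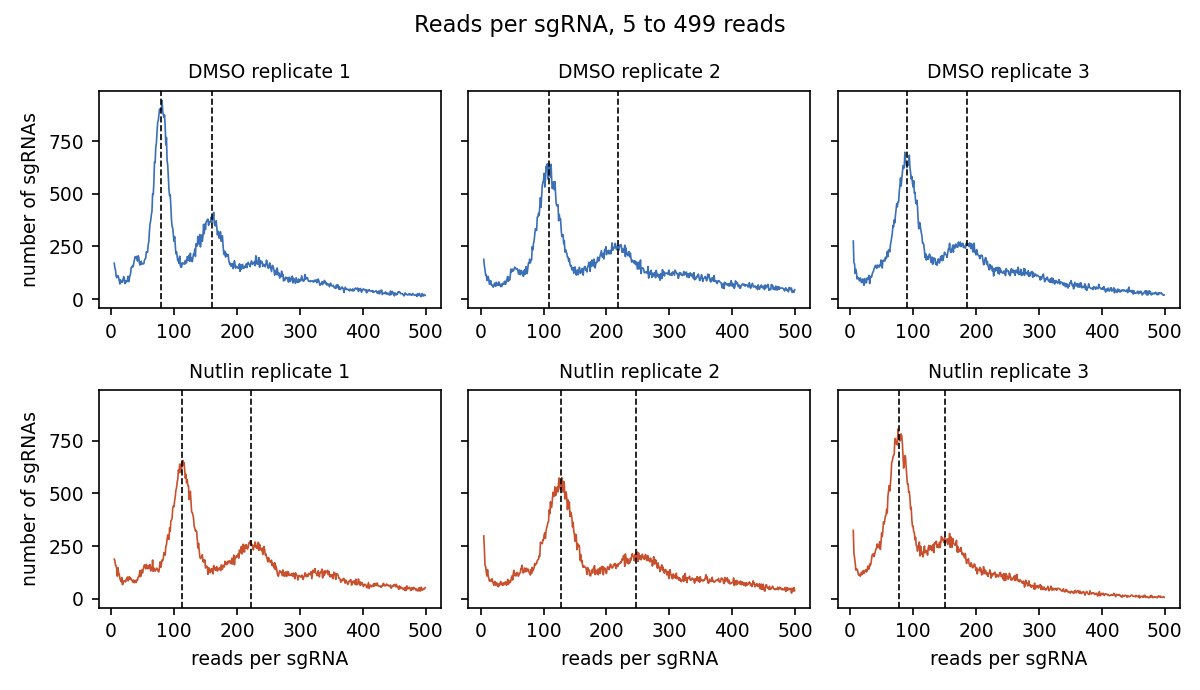
Histograms of reads per sgRNA in the 6 libraries, with the number of sgRNAs on the y axis and reads per sgRNA on the x axis. Each library shows separate peaks, the first at 80, 108 and 90 reads in DMSO and at 113, 127 and 77 reads in Nutlin, and the second at 160, 218 and 186 and at 222, 247 and 150 reads.

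None of the core genes described here passed the threshold in either direction. MDM2, the ubiquitin ligase that Nutlin blocks, was hardly represented, with 2.64 ± 2.43 CPM in DMSO and 8.57 ± 5.21 CPM in Nutlin, and 29 of its 36 values (6 sgRNAs in 6 libraries) were 0. MDM4, a relative of MDM2 that also restrains p53, had 34.7 ± 8.19 CPM in DMSO and 14.4 ± 5.96 CPM in Nutlin (log2 fold change −1.29 ± 0.61, edgeR on summed counts, unadjusted p = 0.0477, adjusted p = 1.00). PPM1D, a phosphatase that dampens p53 signalling, had 26.4 ± 2.02 and 42.5 ± 10.0 CPM, and USP7, a deubiquitinase of MDM2 and p53, had 29.9 ± 10.2 and 27.4 ± 3.19 CPM. TP53BP1 and USP28, which act upstream of p53 after mitotic delay, had 67.1 ± 24.2 and 77.9 ± 28.2 CPM, and 95.5 ± 33.7 and 99.985 ± 36.4 CPM.

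Effectors of p53 gave no call either. CDKN1A, which encodes the cell cycle inhibitor p21, had 50.9 ± 19.1 CPM in DMSO and 54.1 ± 49.6 CPM in Nutlin. The pro-apoptotic genes BAX and BBC3 (PUMA) had 65.4 ± 29.5 and 82.5 ± 28.9 CPM, and 71.8 ± 12.6 and 85.8 ± 25.6 CPM. ATF4, a transcription factor of the integrated stress response, had 32.4 ± 2.403 and 39.4 ± 10.4 CPM, and CDK4, a cell cycle kinase amplified with MDM2 in this tumour type, had 43.2 ± 19.5 and 55.3 ± 11.8 CPM.

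By group, the repressors of p53 averaged 7.26 ± 0.55 CPM per sgRNA in DMSO and 6.85 ± 0.19 in Nutlin, with 9 of 21 genes higher and 12 lower; examples chosen after their values were seen are the deacetylase SIRT1 (44.0 ± 25.9 and 11.5 ± 9.62 CPM) and the ubiquitin ligase HUWE1 (17.4 ± 15.8 and 56.2 ± 3.69 CPM). The arrest and repair targets of p53 had 7.78 ± 0.05 and 8.57 ± 0.73 CPM, with 16 of 24 genes higher, among them XPC, a DNA damage sensor also chosen after its values were seen (44.3 ± 11.003 and 73.3 ± 10.5 CPM). The integrated stress response genes had 6.93 ± 0.39 and 6.97 ± 0.36 CPM, with 13 of 25 higher.

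Genes of the mitochondrial apoptosis pathway averaged 8.82 ± 0.71 CPM per sgRNA in DMSO and 9.63 ± 0.85 in Nutlin, with 10 of 16 higher by summed counts, while camera gave the opposite direction. The anti-apoptotic genes had 9.28 ± 0.41 and 8.37 ± 0.34 CPM, with 6 of 11 lower. BCL2L1, which encodes the survival factor BCL-XL, had 69.4 ± 7.76 and 34.0 ± 6.36 CPM, and MCL1, another survival factor, had 32.8 ± 9.79 and 52.6 ± 19.2 CPM; both were chosen after their values were seen and neither passed. None of the repressors, the arrest targets, the apoptosis genes or the integrated stress response genes passed, and the number adjusted over the list alone was 0 for each of these lists. Camera called none of them (adjusted p = 0.949 for the repressors, 0.734 for the arrest targets, 0.949 for the pro-apoptotic and 0.692 for the anti-apoptotic genes).

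No gene passed the threshold for depletion by rank aggregation, the direction the screen was designed to find. In the 2 kinds of simulated counts this test recovered 0% and 2% of genes lowered 4-fold, and 0% and 42% of genes lowered 10-fold. The absence of calls therefore does not exclude genes whose loss sensitises the cells. Rank aggregation gave 0 depleted genes (1047 at an unadjusted p of 0.05, lowest adjusted p = 0.725), also 0 with the DESeq2 Wald test, and edgeR on summed counts gave 1, ZNF709. The 10 lowest depletion p-values belonged to ALG6, GDF9, CCDC43, ARNT, ZNF709, ZMYND8, TKTL1, EI24, ZNF514 and CDKN2A. ARNT, the partner of the hypoxia-inducible factors, had 232 ± 107 CPM in DMSO and 94.9 ± 6.99 CPM in Nutlin (log2 fold change −1.28 ± 0.27, edgeR on summed counts, adjusted p = 0.619). Of its reads 55.9% came from 1 sgRNA, with 142 ± 106 and 40.5 ± 15.5 CPM. The other ARNT sgRNAs together had 90.0 ± 10.3 and 54.4 ± 18.9 CPM. CDKN2A, which encodes the MDM2 antagonist p14ARF and the CDK4 inhibitor p16, had 135 ± 29.6 and 72.3 ± 28.0 CPM (−0.89 ± 0.32).

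For ZMYND8, a chromatin reader, and ZNF514, a zinc finger protein, 6 of 6 sgRNAs were lower after Nutlin, with 49.8 ± 4.39 and 12.4 ± 12.04 CPM, and 72.9 ± 19.2 and 25.8 ± 9.98 CPM. CCDC43 had 55.1 ± 14.7 and 13.03 ± 11.8 CPM (−2.11 ± 0.58), ALG6, a glucosyltransferase of the N-glycosylation pathway, 79.8 ± 38.4 and 50.1 ± 6.89 CPM, and GDF9, a growth factor of the oocyte, 75.1 ± 11.3 and 33.6 ± 26.3 CPM. ZNF709, another zinc finger gene, had 310 ± 18.9 CPM in DMSO and 113 ± 42.9 CPM in Nutlin (−1.47 ± 0.22, edgeR on summed counts, adjusted p = 0.0152), but 80.2% of its reads came from 1 sgRNA, with 271 ± 16.04 and 68.6 ± 33.9 CPM. The other ZNF709 sgRNAs together had 39.0 ± 2.86 and 44.6 ± 17.0 CPM. TKTL1 and EI24 had 35.5 ± 6.33 and 24.9 ± 5.81 CPM, and 64.0 ± 22.0 and 39.7 ± 12.3 CPM.

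For enrichment, rank aggregation gave 1 gene past the threshold (1046 at an unadjusted p of 0.05), and 0 with ranks from the DESeq2 Wald test. Low enrichment p-values that did not pass belonged to FERMT2, ATXN7L3B, EMC10, HERC2, NUDC, RILP, RAN, TMEFF1 and C12orf71 (lowest adjusted p among these = 0.796). FERMT2, an integrin activator, had 14.8 ± 7.56 CPM in DMSO and 54.5 ± 8.72 CPM in Nutlin. RILP, a lysosome trafficking factor, was higher in 6 of 6 sgRNAs, with 10.98 ± 3.82 and 43.0 ± 19.9 CPM, and ATXN7L3B had 1.72 ± 2.81 and 22.2 ± 5.36 CPM. EMC10, a subunit of a membrane protein insertase, had 47.2 ± 12.3 and 90.7 ± 41.3 CPM, and HERC2, a ubiquitin ligase, 17.3 ± 12.4 and 40.2 ± 2.23 CPM. RAN, the GTPase of nuclear transport, had 6.24 ± 0.14 and 24.98 ± 13.4 CPM, and NUDC, a dynein cofactor, 23.8 ± 21.1 and 44.0 ± 14.6 CPM. For TMEFF1 (34.5 ± 16.7 and 38.2 ± 11.6 CPM) and C12orf71 (27.2 ± 4.44 and 29.8 ± 16.8 CPM) the summed abundance hardly differed although their enrichment p-values were low. Of the 3 tested TMEFF1 sgRNAs 1 was higher and 2 were lower after Nutlin, and of the 6 C12orf71 sgRNAs 5 were higher and 1 was lower.

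**Figure D2:**
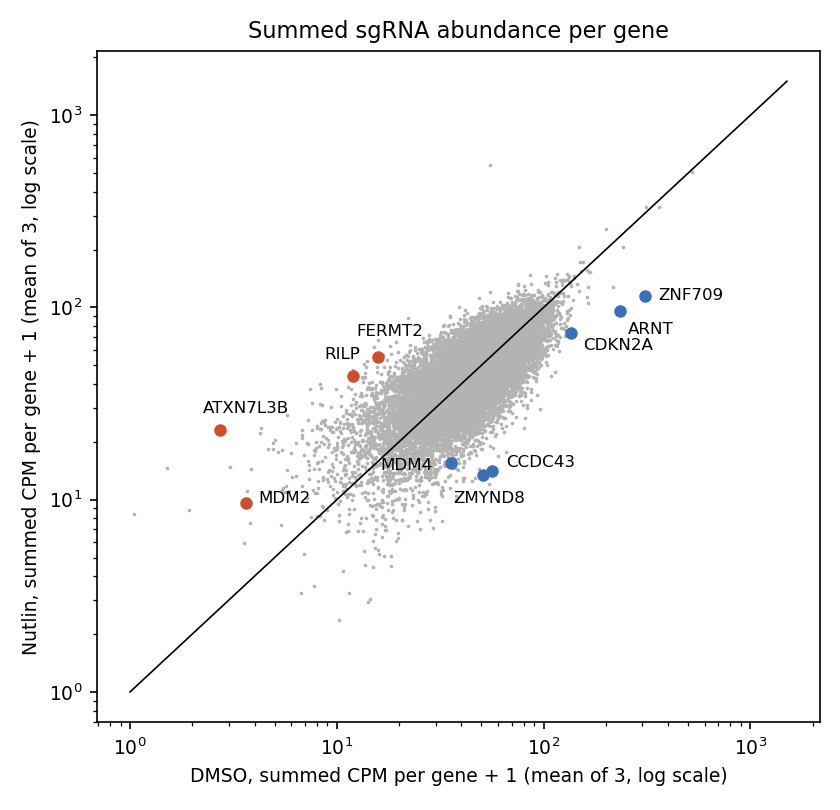
Summed sgRNA abundance per gene, as the mean CPM + 1 of 3 DMSO libraries (x axis, log scale) and of 3 Nutlin libraries (y axis, log scale), with 1 grey point per gene, a line of equal abundance and coloured points for some of the genes named in the text. FERMT2 lies at 14.8 CPM in DMSO and 54.5 CPM in Nutlin, above the line, and ZNF709 at 310 and 113 CPM, below it.

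At the level of single sgRNAs, edgeR called 0 lower and 0 higher after Nutlin, with 1112 and 1165 at an unadjusted p of 0.05. The DESeq2 Wald test called 501 sgRNAs lower and 781 higher. Of these 1282 sgRNAs, 560 (43.7%) had 0 counts in every library of a group, a state shared by 7703 of the tested sgRNAs for exactly one group.

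Camera called 0 of the 37 gene lists higher and 0 lower after Nutlin (2 lists at an unadjusted p of 0.05, 0 called by fry). The DNA replication genes, which include the MCM helicase and the replicative polymerases, came nearest. Their sgRNAs averaged 5.396 ± 0.22 CPM in DMSO and 7.22 ± 0.52 in Nutlin (camera p = 0.00385, adjusted p = 0.142; adjusted p = 0.204 with an estimated correlation), and 38 of 46 genes were higher by summed counts. Examples chosen after their values were seen are MCM6 (13.7 ± 6.53 and 37.2 ± 8.998 CPM) and RRM1, a subunit of ribonucleotide reductase (16.8 ± 8.25 and 44.2 ± 7.14 CPM); neither passed. On a mean z per gene, which corrects less for correlation within a list than camera on sgRNAs, the DNA replication list passed (adjusted p = 0.000262). It also passed by camera with a minimum of 300 counts (adjusted p = 0.0277). Over the settings of camera on sgRNAs its adjusted p reached 0.905, without DMSO replicate 3.

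The mean z per gene also called the cytosolic ribosome and the genes of the 12q13-q15 amplicon higher and the SAGA and histone acetylation genes lower, where camera on sgRNAs called none. The ribosome list had 4.72 ± 0.29 CPM per sgRNA in DMSO and 5.45 ± 0.32 in Nutlin (49 of 78 genes higher; adjusted p = 0.000904 per gene, 0.692 by camera, 0.238 with an estimated correlation). The amplicon list, the region amplified with MDM2 and CDK4 in this tumour type, had 5.63 ± 0.19 and 6.63 ± 0.67 CPM (32 of 40 genes higher; adjusted p = 0.0468 per gene, 0.692 by camera, 0.518 with an estimated correlation). The SAGA and histone acetylation genes had 10.9 ± 0.99 and 8.94 ± 1.06 CPM (16 of 21 lower; adjusted p = 0.0120 per gene, 0.407 by camera, 0.518 with an estimated correlation). In that list TADA1, an adaptor subunit of SAGA, had 216 ± 13.3 and 127 ± 11.3 CPM.

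Over all 20145 genes, 1 passed as enriched and 0 as depleted; adjusted over the list alone, 3 genes passed as enriched and 2 as depleted. The enriched genes included CYP27B1, the vitamin D hydroxylase, in the 12q amplicon (10.4 ± 6.46 and 23.2 ± 2.33 CPM) and CDC16 in the anaphase-promoting complex (32.0 ± 26.4 and 50.6 ± 33.9 CPM). The depleted genes were TADA1 and, among the RB and cyclin D genes, CDKN2A. CYP27B1, CDC16 and TADA1 lie outside the rule for named genes and were chosen after their values were seen.

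By mean abundance with TMM scaling, 24 lists were higher in Nutlin and 13 lower. For 8 lists the 3 Nutlin libraries did not overlap the 3 DMSO libraries, 6 of them above and 2 below, where chance gives 10% of lists; the exact permutation p is then 0.1, the smallest possible with n = 3 per group. The anaphase-promoting complex (5.9995 ± 0.55 and 7.44 ± 0.60 CPM) was among those above, and the anti-apoptotic genes and the end-joining genes were those below. The sign of the level depended on the scaling for 8 lists: Fanconi and homologous recombination, RB and cyclin D, autophagy, proteasome, keratin-associated proteins, olfactory receptors, microRNA targets and the non-targeting sgRNAs. All 8 were lower in Nutlin with TMM and higher with scaling on the non-targeting sgRNAs, so the tally of higher and lower lists depended on the scaling. The median, the mean and the camera direction over the sgRNAs of a list differed in sign for the p53 repressors, the pro-apoptotic genes, the proteasome, translation initiation, RNA polymerase II, Fanconi and homologous recombination, autophagy, olfactory receptors, keratin-associated proteins and microRNA targets.

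**Figure D3:**
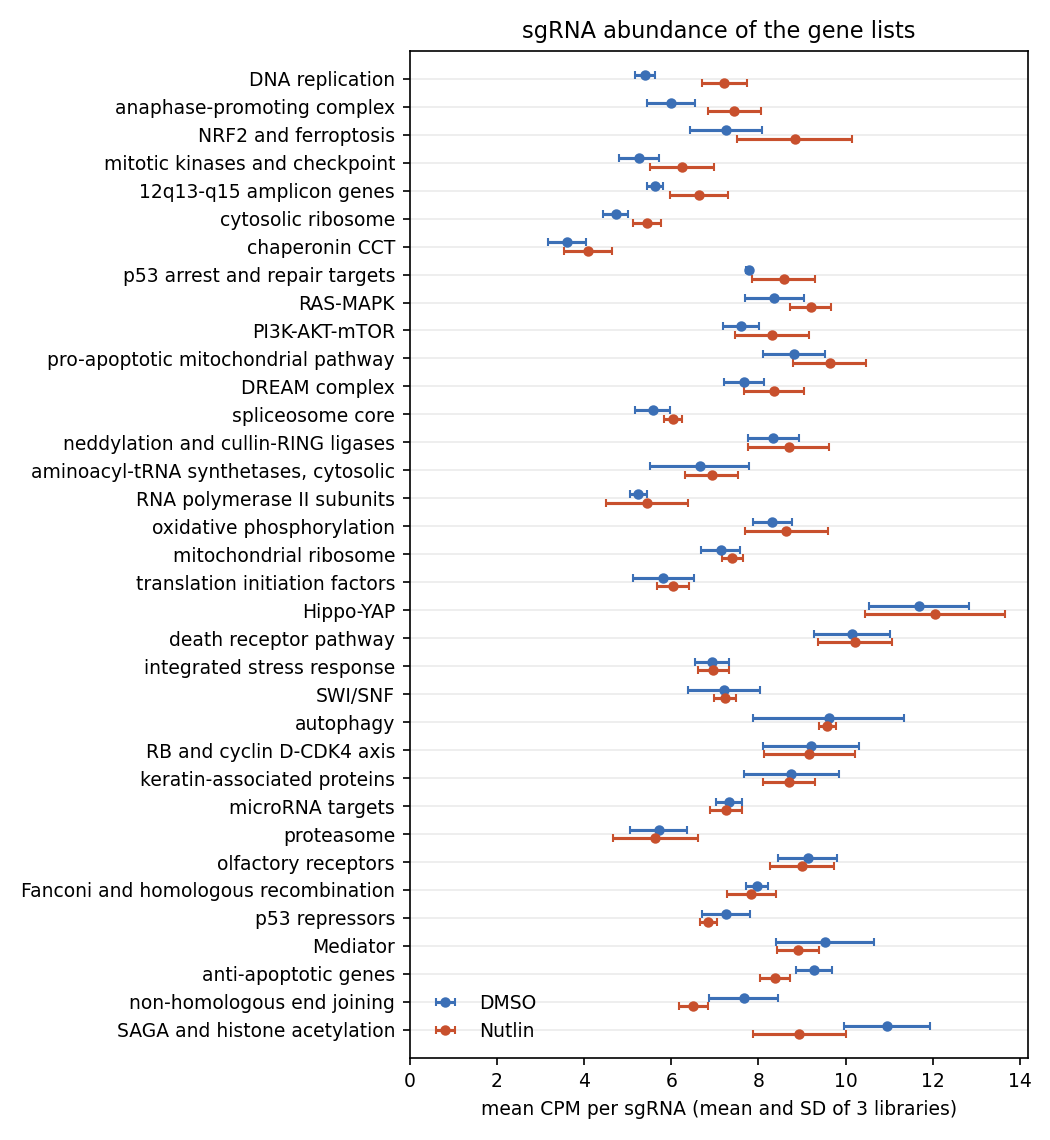
Mean abundance per sgRNA in CPM (x axis) of most of the gene lists (y axis) in DMSO and Nutlin, with points for the mean and bars for the SD of 3 libraries per group. DNA replication genes lie at 5.396 CPM in DMSO and 7.22 CPM in Nutlin, and the SAGA and histone acetylation genes at 10.9 and 8.94 CPM.

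Lists of essential genes were low in DMSO, after the 10 days of growth and 72 h in DMSO. Loss during this time cannot be told apart from low abundance at the start, as the plasmid library and cells sampled before treatment were not used. Set against 10000 random lists of as many genes, the chaperonin CCT genes stood at 48.4% of the random median, the cytosolic ribosome at 57.3%, the mitotic kinases and checkpoint genes at 63.8%, RNA polymerase II at 64.2%, DNA replication at 65.0%, the spliceosome at 67.2%, the proteasome at 68.9%, translation initiation at 69.9% and the anaphase-promoting complex at 72.6%, the last at the 0.13th percentile. The cytosolic aminoacyl-tRNA synthetases stood at 80.5% (1.10th percentile). The genes of the 12q13-q15 amplicon stood at 68.0%, below all 10000 random lists. Oxidative phosphorylation genes were at 99.7% (47.4th percentile) and olfactory receptors, which most tissues do not express, at 110% (99.9th percentile). The SAGA and histone acetylation genes were at 131% (99.4th percentile) and the Hippo and YAP genes at 141% (99.6th percentile).

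The non-targeting sgRNAs had 17.1 ± 0.96 CPM in DMSO and 16.5 ± 0.93 CPM in Nutlin, and their median log2 fold change was −0.03 (quartiles −0.60 and 0.47). This value turned to 0.01 with DESeq2 size factors and to 0.04 with scaling on the non-targeting sgRNAs. With single libraries left out, a choice made after the data were seen, it ran from −0.119 (without Nutlin replicate 2) to 0.0524 (without DMSO replicate 3). The olfactory receptor sgRNAs had 9.13 ± 0.67 and 8.997 ± 0.74 CPM, a difference whose sign also depended on the scaling. The interquartile range of log2 fold changes was 1.59 for them, 1.61 for all tested sgRNAs and 1.07 for the non-targeting sgRNAs. The non-targeting sgRNAs were also the more abundant, and the cause of the differences in abundance and spread was not tested.

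The share of sgRNAs with 0 counts was 24.4% ± 3.24 in DMSO and 23.6% ± 2.47 in Nutlin (SD, n = 3, exact permutation p = 0.8), and 26.2% ± 1.94 and 25.3% ± 1.06 with all libraries thinned to 10624012 reads (exact permutation p = 0.5, n = 3). The Gini index of the counts was 0.575 ± 0.0117 and 0.580 ± 0.0194 (exact permutation p = 0.7, n = 3). The A and B parts of the library, which test the same genes with different sgRNAs, gave median log2 fold changes that correlated with a Spearman rho of 0.0178 across 17824 genes, which are not independent replicates. Among the 200 lowest p-values of each part, 4 genes were shared for enrichment and 1 for depletion. Independent lists drawn only from genes tested in both parts would share 2.95. The lists here were drawn from all genes tested in a part (17301 in A and 15656 in B), so independent lists would share fewer.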

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

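Tests on counts divided by the peak spacing (peak units), tests on sgRNAs with a single matching annotation, and the values of the 0 share, the Gini index and the agreement of the A and B parts without single libraries were chosen after the data were seen. Across scaling, filters and left-out libraries, rank aggregation gave 1 enriched gene and 0 depleted genes in each setting. Genes depleted were 1 (ZNF709) with counts summed per gene and 1 with peak units summed per gene. Genes enriched were 0 with ranks from the DESeq2 Wald test, 0 when ranked by log2 fold change and 0 in the A part alone, and 2 with peak units summed per gene, among them LAMTOR2 (2.25 ± 0.48, edgeR adjusted p = 0.0407), chosen after its values were seen. sgRNAs lower and higher were 501 and 781 with DESeq2 and 2 and 4 with peak units. Lists lower were 1 and lists higher 3 on a mean z per gene, and lists higher 1 with a minimum of 300 counts. The cause of these differences was not tested.

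The correlations of deviations gave no sign that the replicate numbers pair the samples. They were 0.00401, −0.0099 and 0.0111 between libraries of the same number and −0.0174 to 0.0147 between those of different numbers. They cannot exclude pairing, because in peak units the spread between replicates was close to that of Poisson counts. With the replicate block, edgeR called 1 sgRNA lower and 1 higher, 0 genes depleted (lowest adjusted p = 0.0806) and 1 enriched, the agreement of the A and B parts was 0.0059, and the block changed no other call. That agreement was 0.00457 with a minimum of 300 counts, and 0.00678 to 0.0133 with each library left out.

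Without single libraries the difference in the 0 share ran from −1.78 (without DMSO replicate 3) to 1.06 percentage points (without DMSO replicate 1), and it was 0.606 without Nutlin replicate 2. The difference in the Gini index ran from −0.00548 (without Nutlin replicate 3) to 0.0138 (without Nutlin replicate 1), and it was −0.000568 without DMSO replicate 1. Of 31 named genes, 21 kept the sign of their median log2 fold change in every setting that gave a value; some, such as MDM2, gave none with a minimum of 300 counts. For the other 10, none of them called by rank aggregation (ZNF709 was called on summed counts), the range with each library left out was −0.52 to 0.76 for BAX, −0.40 to 0.79 for BBC3, −0.43 to 1.17 for CDK4, −1.21 to 0.63 for CDKN1A, −2.04 to 1.00 for PPM1D, −1.44 to 0.33 for TP53BP1, 0.07 to 1.28 for USP7, −1.82 to 0.0375 for GDF9, −0.94 to 0.25 for ZNF709 and −2.79 to 1.17 for TKTL1. The sign also turned with size factors for BBC3 (0.0592) and TKTL1 (0.0257), with total counts for BBC3 (0.0293) and TKTL1 (0.0536), and with a minimum of 300 counts for BBC3 (0.29), PPM1D (1.23) and USP7 (−0.29); the cause was not tested. At this depth, in simulated peak-unit counts, rank aggregation recovered 84% of genes raised 4-fold and 2% of genes lowered 4-fold. With negative binomial counts it recovered 28% and 0% of these classes.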

Other observations

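The tests of few templates, of essential genes around MDM2 and of the scaling between libraries were chosen after the result was seen. sgRNAs against genes of the PI3K, AKT and mTOR pathway averaged 7.604 ± 0.41 CPM in DMSO and 8.31 ± 0.84 in Nutlin, with 16 of 25 genes higher by summed counts (camera adjusted p = 0.692). MTOR, the kinase of both mTOR complexes, was chosen after its values were seen (27.7 ± 2.51 and 53.1 ± 4.51 CPM) and did not pass the threshold. The end-joining genes averaged 7.66 ± 0.79 and 6.50 ± 0.34 CPM (camera adjusted p = 0.692), with 7 of 12 genes lower. LIG4, the ligase of that pathway and likewise chosen after its values were seen, had 82.0 ± 18.4 and 30.02 ± 10.8 CPM and did not pass.

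In every library the reads per sgRNA clustered at multiples of one value. Too few reads do not account for the spread between replicates, since thinning to 10% of the reads lowered the mean Spearman correlation of gene sums between replicates by 0.0196, from 0.522 to 0.503. In reads, the variance over the mean between replicates was 98.8 in DMSO and 110 in Nutlin, and in units of the peak spacing it averaged 1.09, close to that of Poisson counts. A candidate explanation is that few template genomes per sgRNA entered the amplification, with 1.17 to 1.54 peak units per sgRNA and library. Differences between cultures were not tested separately, and no biological explanation was tested.

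Genes were ordered by the GRCh38.p14 annotation into overlapping runs of 15 neighbouring genes. In values pooled over the 6 libraries, the lowest sgRNA abundance of 17977 such runs was shared by several runs on chromosome 12. The run centred on MDM2 was among these (percentile 0.0334 with ties counted) and is described as the first in gene order. Its median was 3.75 CPM per sgRNA (47.1% of the median gene). Of the 20 lowest runs, 11 were centred on chromosome 12, but neighbouring runs share genes, so these are not independent. The runs centred on CDK4 and HMGA2, on the same chromosome, stood at percentiles 6.998 and 13.79. The lowest genes of the run centred on MDM2 were MDM2 (0.926 CPM per sgRNA), the carboxypeptidase gene CPM (2.44) and CCT2 (2.93). That run stood at 43.7% ± 2.55 of the gene median in DMSO and 62.7% ± 17.5 in Nutlin (SD, n = 3). Nutlin replicate 1 was at 81.9% and percentile 11.55, against a percentile of at most 0.300 in the other libraries. sgRNAs that match several genes do not account for the low abundance of that run. With sgRNAs annotated to their target alone the best rank of the runs centred on its genes was 1, that of the run centred on MDM2 itself. Tied runs were ranked in gene order here as well. Essential genes in the run cannot be told apart: without the genes of the essential lists and the named amplicon drivers the 10 genes left were at percentile 7.37 of runs of as many genes (6.41 CPM), but all 5 genes removed lay at or below the median of the run, so that removing them had to raise it. Uneven representation in the plasmid library cannot be told apart, as the plasmid was not used here and the run stood at percentiles 0.0667 in the A part and 1.37 in the B part; copy number was not measured.

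With TMM scaling, the mean sgRNA abundance was higher after Nutlin in 9 of 10 lists of essential genes and in 24 of all 37 lists. Camera on sgRNAs with at least 60 counts called none of them, and 7 of 11 RNA polymerase II genes were lower. On a mean z per gene the DNA replication, cytosolic ribosome and 12q13-q15 amplicon lists passed. The tally of higher lists depended on the scaling, and the proteasome turned from a log2 ratio of −0.018 (TMM) to 0.054 (non-targeting sgRNAs). Scaling does not account for the rise of essential-list sgRNAs relative to olfactory receptor sgRNAs, a ratio taken within each library. This ratio was higher in all 3 Nutlin libraries, 59.1% in DMSO and 67.7% in Nutlin (a log2 difference of 0.197, exact permutation p = 0.1, the smallest possible). A candidate explanation is that cells held back by Nutlin divided less, which would leave depleted sgRNAs less depleted. Its test gave a log2 difference of 0.053 between the 10% of genes lowest in a left-out DMSO library and the other genes, with 0.0355 and 0.0695 as the lowest and highest of the 3 left-out libraries. The hypothesis was tested on the same data and remains open.

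The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. A count as large as the real one came in 2 of the 10 splits for enriched genes (real 1, highest other 1, counting each split with its groups in either order). It came in 10 of the 10 splits for depleted genes (real 0, highest other 1). The same held for sgRNAs and for lists in either direction (real 0, highest other 0). With a real count of 0 every split gives a count as large, so these comparisons decide nothing.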
